A study of Rattus norvegicus with 82 samples.

How the data were processed

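The series measured total RNA from rat brain on 82 arrays with 31099 probe sets each. Per the labels, the arrays came from 7 regions (frontal cortex, septum, hypothalamus, amygdala, hippocampus, dorsal raphe and locus coeruleus), 3 treatments (Sham, ADX and pADX) and 2 times of day (AM and PM). The labels do not spell out the treatments. ADX is the usual short form of adrenalectomy, removal of the adrenal glands, and Sham of the control operation; what the letter p before ADX stands for is not given in the sources used here. Titles that end in a letter b were taken as replicate 2 and titles without it as replicate 1. In all, 80 arrays fell into 41 groups of region, treatment and time, each of 2 arrays except frontal cortex Sham AM and frontal cortex ADX AM, which held 1. The hippocampus had no pADX array labelled AM, since both of its pADX arrays are labelled PM. In the order of the series both stand where the other regions have pADX AM, so their time of day is in doubt, and with it the hippocampal results for pADX and for PM vs AM. The other 2 arrays, both of frontal cortex, carry no treatment and entered no comparison. Region was read from the title and the description. The source name disagreed with these for the septum, dorsal raphe and locus coeruleus (frontal cortex as source) and for the hypothalamus (hippocampi as source).

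The deposited values are 1 linear intensity per probe set and array, positive and skewed, as their distribution shows; the software and the scaling are not given in the sources used here. The values showed 2 scaling states. In 45 arrays the mean after trimming 2% at each end lay between 150.04 and 150.05, and in the other 37 it ranged from 34.1 to 171. All arrays of the frontal cortex, septum and amygdala were at the common value and none of the hypothalamus or hippocampus. In the locus coeruleus 4 of 4 Sham, 0 of 4 ADX and 3 of 4 pADX arrays were at it, and in the dorsal raphe 2 of 4 Sham and 0 of 4 of each other treatment. Both of those dorsal raphe Sham arrays were PM, so within Sham scaling state and time of day coincided there. No model held a term for the scaling state, and only the normalization between arrays adjusted for it. For most named genes of ADX vs Sham across regions, values from the septum and amygdala, which share a scale, are given beside the pooled ones. Median signal per array ran from 13.9 to 61.8, and the ratio of 3' to 5' GAPDH probe sets from 0.946 to 1.40. The same ratio for beta-actin ran more widely and differed between regions. It lay between 1.73 and 2.95 in the hippocampus and between 3.12 and 6.03 in the dorsal raphe. No model held a term for it. For arrays the number of samples limits the precision.

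Because the distributions differed, the deposited values were quantile normalized over the 82 arrays, set to a floor of 16 and put on the log2 scale, where the floor is 4. A change against a group with arrays at the floor is a lower bound, written "at least". After this 27.5% of values lay at the floor. The 57 control probe sets were left out and the other 31042 tested without a filter. Of these, 20826 carried 1 gene symbol in the platform's annotation, 436 carried several and 9780 none; 20758 were matched by gene identifier to the RefSeq gene table of assembly GRCr8, used for names only, and 14217 genes were named.

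The labels do not say whether arrays come from separate animals or pools, or whether 1 animal gave several regions. For comparisons across regions, the log2 values of the 5 regions with all 12 arrays (septum, hypothalamus, amygdala, dorsal raphe, locus coeruleus) were therefore averaged into 12 units, 1 for each combination of treatment, time of day and replicate. Adjusted p-values below measure spread between these units or arrays. limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) fitted treatment and time of day as additive terms, and 6 means of treatment by time for the comparisons within a treatment or time and for the interactions. Probe sets passed at a Benjamini-Hochberg adjusted p of 0.05. Each region was fitted alone in the same way. Differences among regions were tested with limma's moderated F test over the 80 grouped arrays with the 12 combinations as a fixed block, and probe sets were called highest in a region when the F test passed and the region's mean exceeded every other by 1 log2 unit. Whether a treatment or time change differed between regions was tested by an interaction F test over the same arrays. Fold changes are given as the higher over the lower group.

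The treatment and time of day comparisons, ADX by time of day, the region tests, the rule that led to quantile normalization and the floor, the gene lists and the rule for named genes were set before the data were examined. The comparisons within a treatment or within a time of day, pADX by time of day, the interactions by region and the separate adjustment of gene lists and marker lists were added later. Named genes are the 10 that rose and the 10 that fell most in each comparison across regions (5 and 5 in a single region) among probe sets past the threshold with 1 symbol and a mean at or above the 40th percentile of probe sets, 1 probe set per gene, plus list members past the threshold. Each region's largest leads, at most 5, are named too. Of its fixed markers only a part is named, with a count of those highest in their own region. Fkbp5, Sgk1, Tsc22d3, Per1, Nr3c1, Nr3c2, Dbp, Per2, Nr1d2 and Bmal1 are given whatever their result, as are Crh and Avp in the hypothalamus, Slc6a4 in the dorsal raphe and Th and Dbh in the locus coeruleus; Tph2, also on that list, was not measured by a probe set with a symbol.

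Of 367 listed genes, 324 were measured. The 8 gene lists were glucocorticoid-induced genes, corticosteroid receptors and the hypothalamic-pituitary-adrenal (HPA) axis, circadian clock genes, monoamine genes, neuropeptide genes, immediate early genes, glutamate and GABA receptors, and trophic factors and receptors. The 13 marker lists were oligodendrocyte, astrocyte, microglia and macrophage, endothelial cell, neuron, choroid plexus, ependyma, meninges and fibroblast, blood, pituitary, cerebellum, striatum and thalamus; 1 further marker list was set for each of the 7 regions. A list used 1 probe set per gene, the one with the highest mean. Its members were counted after adjustment over all probe sets and adjusted over the list alone, and each list was tested against the other genes with limma's camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 8 gene lists or over the 13 marker lists of a comparison.

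The fits were tested on simulated data built from the real means and spread. The changed probe sets were drawn only from those at or above the 40th percentile of mean signal. Recovery among dimmer probe sets was not tested. Across regions they recovered 100% of probe sets changed by 2 log2 units, 100% of those changed by 1 and 78% of those changed by 0.5, with 10 false calls; in the septum alone 90%, 56% and 10% with 11 false calls. In the frontal cortex alone, with fewer arrays, they recovered 78% and 26% at 2 and 1 log2 units and, at 0.5, 8% of falls and 10% of rises, with 6 false calls. Of interactions of 1 log2 unit between ADX and time of day, 59% were recovered with 7 false calls. The alternatives set beforehand were median scaling, a floor 4 times higher, a filter on dim probe sets, a variance prior without a trend, the replicate number as a block, 6 means in place of additive terms, each region left out, all 80 arrays with limma's duplicateCorrelation, 1 model over all 80 arrays, a mean of all probe sets of a gene, a lead of 2 log2 units, and each unit or array left out in turn. Values as deposited, the septum, hypothalamus and amygdala alone, and the interactions without 1 frontal cortex array or without the frontal cortex were added after seeing the data. No overlap of calls between ADX and pADX, which share the Sham arrays, was counted; ADX was compared with pADX directly.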

Results

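The 80 grouped arrays held 12 from each of the septum, hypothalamus, amygdala, dorsal raphe and locus coeruleus and 10 from each of the frontal cortex and hippocampus. With treatment, each region had 4 Sham, 4 ADX and 4 pADX arrays, except the frontal cortex with 3 Sham and 3 ADX and the hippocampus with 2 pADX, whose PM label is in doubt. The correlation of an array with the mean of its region ran from 0.951 to 0.989; the lowest belonged to frontal cortex Sham PM replicate 2. The labels pose 3 questions: what ADX and pADX did to gene expression in the brain against Sham, whether expression differed between PM and AM, and how the regions differed in both.

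Across 5 regions, ADX tissue held less RNA of genes that glucocorticoids are known to induce. Sult1a1, a phenol sulfotransferase, fell most, with a mean log2 signal of 7.20 (SD 0.26, n = 4 units) in Sham and 5.15 (SD 0.15, n = 4) in ADX, 4.17-fold lower. Glul, the glutamine synthetase of astrocytes, fell 1.34-fold (log2 change -0.43, SE 0.06). The metallothionein Mt2A fell 1.36-fold (-0.44, SE 0.06) and Ndrg2, abundant in astrocytes, 1.22-fold (-0.29, SE 0.03). In the list of glucocorticoid-induced genes, 4 of 41 measured members fell (Sult1a1, Mt2A, Glul and Ndrg2) and none rose. There were 13 that fell adjusted over the list alone, among them Gpd1 (-1.21), Angptl4 (-0.65), Ccn2 (-0.50), Pdk4 (-0.48), Dusp1 (-0.35) and Fkbp5 (-0.34). The change was negative in 34 members and positive in 5, with a median of -0.15 log2 units. Camera called the list down (adjusted p = 8e-16; adjusted p = 0.0303 with an estimated correlation), and its preset call held in all 26 alternatives.

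Genes outside that list changed as well. Htra1, a secreted serine protease, fell 2.15-fold (-1.10, SE 0.08). Alas2, which starts heme synthesis in developing red cells, fell at least 3.08-fold (-1.62, SE 0.20, adjusted p = 0.0304; 6 of 20 ADX arrays at the floor), and Heph, a copper ferroxidase that exports iron, fell at least 1.94-fold (-0.95, SE 0.12; 1 ADX array at the floor). Prodh, the first enzyme of proline breakdown, fell 1.83-fold (-0.87, SE 0.09) and Pygm, a glycogen phosphorylase, fell too (-0.58, SE 0.07). Aifm3, a mitochondrial protein related to apoptosis-inducing factor, fell 1.66-fold, Phyhd1, a dioxygenase of the phytanoyl-CoA hydroxylase family, 1.64-fold, Paqr8, a membrane progestin receptor, 1.56-fold and the chemokine Cxcl12 1.43-fold. Another well detected probe set of Cxcl12 had a change of -0.06 (adjusted p = 0.894). Igfbp5, which binds insulin-like growth factors, rose 1.60-fold (0.68, SE 0.09), as did Olfml1 (0.68, SE 0.09), and Lix1 rose 1.33-fold (0.41, SE 0.05). Smaller rises were found for Snapc2, part of a complex that transcribes small nuclear RNAs (0.23), the clock repressor Bhlhe41 (0.14) and the cyclin-like Ccnyl1 (0.13).

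**Figure D1:**
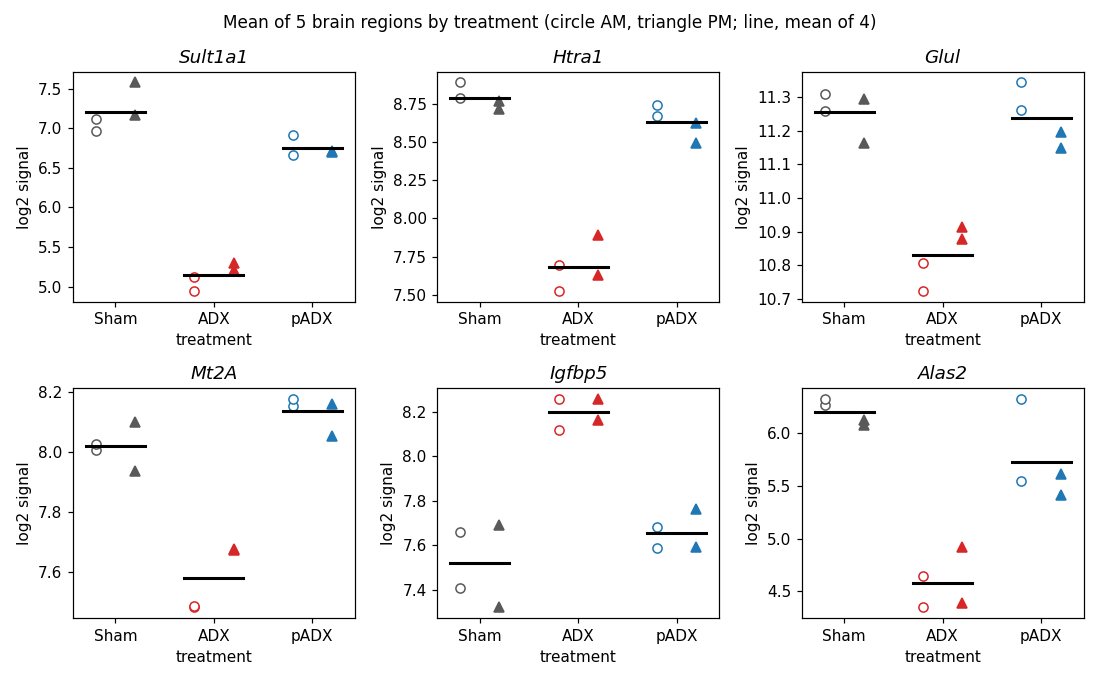
Log2 signal (y axis) of 6 genes by treatment (x axis), where each point is 1 unit, the mean of 5 brain regions for 1 treatment, time of day and replicate (circles AM, triangles PM), and each line the mean of 4 units. The Sult1a1 units of ADX lie near 5.15 and those of Sham near 7.20.

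The other gene lists moved little. Of corticosteroid receptor and HPA axis genes, 0 of 16 passed in limma. Adjusted over the list alone, the mineralocorticoid receptor gene Nr3c2 rose (0.25) and the vasopressin receptor gene Avpr1a (-0.26, with 16 of 60 arrays at the floor) and Hsd11b1, which regenerates active glucocorticoid (-0.31), fell. The glucocorticoid receptor gene Nr3c1 stood at 0.12 (adjusted p = 0.701). Among 21 clock genes 1 rose (Bhlhe41), and Dbp (0.31) rose too when adjusted over the list alone. Adjusted over the list alone, the serotonin receptor gene Htr2a (-0.34) of 26 monoamine genes, Vip (-0.34) of 25 neuropeptide genes and Fgfr1, Igf1r and Ntrk2 (-0.14 to -0.20) of 15 trophic factor genes fell. No member of the 21 immediate early genes or 29 glutamate and GABA receptor genes passed either way. Camera called none of these 7 lists (adjusted p from 0.454 to 0.958). Median, mean and camera direction differed in sign for the neuropeptide list (0.00, 0.01, down), the immediate early list (0.01, 0.01, down) and the receptor list (-0.03, 0.01, down).

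Of the blood markers, 1 of 5 fell (Alas2), and adjusted over the list alone the beta globin gene Hbb fell too (-1.73, SE 0.27, adjusted p = 0.066 over all probe sets). The list median was -0.31, its mean -0.77, and camera called it down (adjusted p = 0.00013; adjusted p = 0.14 with an estimated correlation). The Alas2 change was negative in each region and passed in none alone. No Alas2 array was at the floor in the dorsal raphe (-1.30), frontal cortex (-1.96) or hypothalamus (-1.94). In the septum, amygdala, hippocampus and locus coeruleus 3, 2, 2 and 1 of 4 ADX arrays were, so the changes there (-1.41, -1.70, -1.90 and -1.77) are lower bounds on the size of the fall. Camera called no other marker list (adjusted p from 0.223 to 0.767), with medians of 0.05 for oligodendrocyte, -0.07 for astrocyte, 0.08 for microglia and macrophage, 0.09 for endothelial cell, 0.03 for neuron, 0.07 for choroid plexus, 0.03 for ependyma, 0.02 for meninges and fibroblast (camera direction down), -0.01 for pituitary, -0.09 for cerebellum, 0.05 for striatum and -0.06 for thalamus. When adjusted over the list alone, the myelin genes Mag and Ugt8 rose while Mal and Mobp fell, and the astrocyte filament gene Gfap (0.39) and the endothelial transporter gene Slco1a4 (0.21) rose.

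For ADX vs Sham across regions limma called 41 probe sets, 11 that rose and 30 that fell, of 31042 tested; 9 had a mean below the 40th percentile. All 4 ADX units lay beyond all 4 Sham units for 17 of the 17 named genes whose unit values came from the named probe set, where chance gives 2.86% for genes not chosen by their difference. These genes were chosen on the same units, so the count is not independent evidence. The calls of Sult1a1 (adjusted p = 0.000554), Htra1 (0.00207), Phyhd1 (0.00287) and Paqr8 (0.00531) held in all 26 alternatives, that of Ndrg2 (0.00739) in 24 (lost without Sham AM replicate 2) and that of Prodh (0.0149) in 21 (lost without Sham PM replicate 1, Sham AM replicate 2 or Sham PM replicate 2). The other 13 named genes (adjusted p from 0.0304 to 0.0435) kept theirs in 5 to 12, and each lost it without at least 9 of the 12 units. Left out in turn, single units changed the count to 25 without Sham AM replicate 1, 8 without Sham AM replicate 2, 15 without Sham PM replicate 1, 16 without Sham PM replicate 2, 13 without ADX AM replicate 1, and 19 without ADX AM replicate 2. It was 43 without ADX PM replicate 1, 16 without ADX PM replicate 2, 17 and 19 without pADX AM replicates 1 and 2, and 22 without pADX PM replicate 1 or 2. In the septum, hypothalamus and amygdala alone 17 probe sets were called, 0 up and 17 down. These 3 regions do not share a scale, since no hypothalamus array was at the common value and its trimmed means ran from 94.2 to 118 in Sham and from 73.6 to 96.4 in ADX. There Sult1a1 (-2.19), Htra1 (-1.22), Phyhd1 (-0.72), Paqr8 (-0.71), Ndrg2 (-0.28), Glul (-0.44) and Alas2 (-1.68, a lower bound of its fall) kept their calls. All 6 named rises lost theirs: Igfbp5 (0.50, adjusted p = 0.153), Olfml1 (0.58, 0.162), Lix1 (0.37, 0.117), Snapc2 (0.15, 0.501), Bhlhe41 (0.21, 0.0568) and Ccnyl1 (0.15, 0.428). So did Heph (-0.82, a lower bound of its fall, adjusted p = 0.144), Prodh (-0.85, 0.0978), Pygm (-0.61, 0.15), Aifm3 (-0.77, 0.117), Cxcl12 (-0.52, 0.0543) and Mt2A (-0.32, 0.296). In the septum and then the amygdala, which share a scale, the rises stood at 0.57 and 0.31 for Igfbp5, 0.72 and 0.29 for Olfml1, 0.27 and 0.33 for Lix1, 0.51 and -0.19 for Snapc2, 0.36 and 0.14 for Bhlhe41 and 0.10 and 0.30 for Ccnyl1. The falls stood at -0.54 and -0.95 for Heph, -0.74 and -0.72 for Prodh, -1.13 and -0.48 for Aifm3, -0.84 and -0.62 for Phyhd1 and -0.68 and -0.71 for Paqr8. The -0.95 of Heph is a lower bound of its fall, with 1 amygdala ADX array at the floor. As deposited, the median of all probe sets was -0.21. On that scale Snapc2 (-0.06), Bhlhe41 (-0.16), Ccnyl1 (-0.16), Nr3c1 (-0.17) and Nr3c2 (-0.04) turned negative. Sgk1 (-0.68, adjusted p = 0.541), Tsc22d3 (-0.21), Per1 (-0.42; 22 of 60 arrays at the floor), Per2 (0.07), Nr1d2 (0.14), Bmal1 (-0.20) and Fkbp5 (adjusted p = 0.369) did not pass over all probe sets.

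In pADX against Sham, none of the genes given for every comparison passed the test. Sult1a1 had a mean of 6.75 (SD 0.11, n = 4) in pADX. Fkbp5, a glucocorticoid-induced co-chaperone, stood at -0.10 (adjusted p = 0.868), the kinase gene Sgk1 at -0.31 (0.857), Tsc22d3 at -0.03, Per1 at -0.10, Nr3c1 at 0.10, Nr3c2 at 0.07, Dbp at 0.21 (0.491), Per2 at -0.05, Nr1d2 at 0.10 and Bmal1 at -0.10 (0.813). Of the 41 glucocorticoid-induced genes none passed across regions, over all probe sets or adjusted over the list alone, and the list had a median of -0.03 (camera adjusted p = 0.0752). Within single regions, adjusted over the list alone, Fkbp5 fell in the frontal cortex (mean 6.81 in pADX, 7.47 in Sham). Sult1a1 fell in the septum (6.56 and 7.46), and no member passed so in another region. On that basis 4 of 29 glutamate and GABA receptor genes rose and 3 fell in the frontal cortex, where Adra2c and Ntrk2 fell too. Across regions the following held. The tight junction gene Cldn5 (-0.11) and the endothelial adhesion gene Esam (-0.19) fell when adjusted over the list alone. Camera called the trophic factor list down (median -0.05, adjusted p = 0.0267), with no member past the threshold; with an estimated correlation it had an adjusted p = 0.318, and the preset call was kept in 15 of 26 alternatives. No other list was called.

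For pADX vs Sham across regions limma called 2 probe sets, 1 up and 1 down, both with a mean below the 40th percentile; 2391 had an unadjusted p under 0.05. The count was 8 without Sham AM replicate 1, 3 without ADX AM replicate 1 or Sham PM replicate 1, and 1 without pADX AM replicate 1, ADX PM replicate 1, Sham AM replicate 2, ADX AM replicate 2, Sham PM replicate 2 or pADX PM replicate 2. Without Sham PM replicate 1 the Sgk1 change was 0.00.

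Set directly against pADX, ADX showed lower levels of 8 named genes and higher levels of 2. Sult1a1 fell 3.03-fold (-1.60, SE 0.12, adjusted p = 0.00482), Htra1 1.93-fold (-0.95), Prodh 1.73-fold (-0.79), Phyhd1 1.53-fold (-0.62), Mt2A 1.47-fold (-0.56), Paqr8 1.44-fold (-0.52) and Ndrg2 1.23-fold (-0.30). Sfrp1, a secreted antagonist of Wnt signalling, fell at least 1.35-fold (-0.44, adjusted p = 0.0175; 2 ADX arrays at the floor), while Bhlhe41 (0.15) and Ccnyl1 (0.14) rose. Of the glucocorticoid-induced genes 3 of 41 fell (Sult1a1, Mt2A, Ndrg2). In all 8 fell adjusted over the list alone, with Angptl4 (-0.55), Dusp1 (-0.40), Glul (-0.41), Net1 (-0.25) and Sesn1 (-0.14). On the same basis 1 rose, Lyve1 (0.33, with 9 of 60 arrays at the floor), a hyaluronan receptor of lymphatic vessels and macrophages. Camera called the list down (median -0.17, adjusted p = 2.71e-10; adjusted p = 0.0985 with an estimated correlation).

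The direct comparison also set some cell type markers apart. Camera called oligodendrocyte markers up (median 0.09, adjusted p = 0.0022), microglia and macrophage markers up (0.12, adjusted p = 0.00852) and blood markers down (-0.28, adjusted p = 0.00334). Each had an adjusted p = 0.405 with an estimated correlation. As deposited the first 2 medians stood at -0.09 and -0.02, both above the median of all probe sets on that scale (-0.12). Over all probe sets no marker passed. With p adjusted over the list alone, Mag (0.21), the macrophage growth factor receptor gene Csf1r (0.22), Gfap (0.26), Slco1a4 (0.25), Esam (0.19) and Cldn5 (0.12) rose, and Hbb (-1.28), Alas2 (-1.15), the connexin gene Gjb6 (-0.32) and Fgfr3 (-0.11) fell, as did Hsd11b1 (-0.29) of the HPA axis list. The size of the Alas2 fall is not exact, since 6 ADX arrays and 1 pADX array were at the floor. The ependyma markers had a median of 0.05, a mean of -0.01 and camera direction down.

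For ADX vs pADX across regions limma called 15 probe sets, 4 that rose and 11 that fell, and all 4 ADX units lay beyond all 4 pADX units for 10 of 10 named genes. The chance share of 2.86% holds for genes not chosen by their difference, and these were chosen on the same units. The calls of Htra1 (adjusted p = 0.00928) and Phyhd1 (0.00976) were lost without ADX AM replicate 2 and without pADX AM replicate 2, and that of Ndrg2 (0.00976) without these and without ADX AM replicate 1. Mt2A lost its call without 5 of the 12 units, and Paqr8, Prodh, Sfrp1, Bhlhe41 and Ccnyl1 without 8 to 12. As deposited, Bhlhe41 and Ccnyl1 stood at -0.02 and -0.03, both above the median of all probe sets on that scale (-0.12). The count was 28 without ADX PM replicate 1, 9 without Sham PM replicate 2, 6 without ADX AM replicate 1, pADX AM replicate 1 or Sham AM replicate 2, and 4 without ADX AM replicate 2 or pADX AM replicate 2. Fkbp5 (-0.24, adjusted p = 0.625), Sgk1 (-0.38, 0.807) and Nr3c2 (0.18, 0.458) did not pass.

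Within Sham, 5 named genes were higher at PM than at AM and 5 were lower. Gpd1, a glycerol-3-phosphate dehydrogenase, rose 2.59-fold from AM to PM (log2 change 1.38, SE 0.11, n = 2 units per time, adjusted p = 0.0139). Dbp, a transcription factor under clock control, rose 1.26-fold (0.33, SE 0.03, adjusted p = 0.0392). Adipor2, an adiponectin receptor gene (0.60), the lipid phosphatase gene Mtmr2 (0.50) and Rrp8, which methylates ribosomal RNA (0.57), also rose. The matrix protease gene Mmp14 fell 1.91-fold (-0.93, adjusted p = 0.0201), and the monocarboxylate transporter gene Slc16a1 (-0.33), Cnot10 of the deadenylase complex (-0.28), the taurine transporter gene Slc6a6 (-0.27) and Gtf2i (-0.16) fell. Another well detected probe set of Gtf2i stood at 0.06. In the septum and amygdala alone, which share a scaling state, Gpd1 stood at 1.16 and Dbp at 0.21. For the other named genes no such values are given. In the dorsal raphe both Sham PM arrays and no Sham AM array were at the common scale, so scaling and time coincided there.

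Of the 41 glucocorticoid-induced genes 1 rose in Sham from AM to PM (Gpd1). In the same list 9 rose adjusted over the list alone, among them Sgk1 (1.11), Ddit4 (0.67), Plekhf1 (0.47), Tsc22d3 (0.43) and Klf9 (0.39), and Tgm2 (-0.46) fell. Camera called the list up (median 0.09, adjusted p = 1.08e-06; adjusted p = 0.0832 with an estimated correlation). Adjusted over the list alone, 4 of 21 clock genes rose (Per2 0.55, Per1 0.48, Dbp 0.33, Nr1d2 0.26) and 4 fell (Bmal1 -0.30, Npas2 -0.28, Nr1d1 -0.22, Clock -0.19), with 1, Dbp, past the threshold over all probe sets and a camera adjusted p of 0.0535. Of 21 immediate early genes none passed over all probe sets and 5 rose adjusted over the list alone (Fos 0.61, Egr1 0.41, Dusp6 0.29, Junb 0.23, Jun 0.18); camera called the list up (median 0.11, adjusted p = 4e-05; adjusted p = 0.0419 with an estimated correlation). Oligodendrocyte markers were called down (median -0.11, adjusted p = 0.00186; adjusted p = 0.817 with an estimated correlation) with no member past the threshold.

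**Figure D2:**
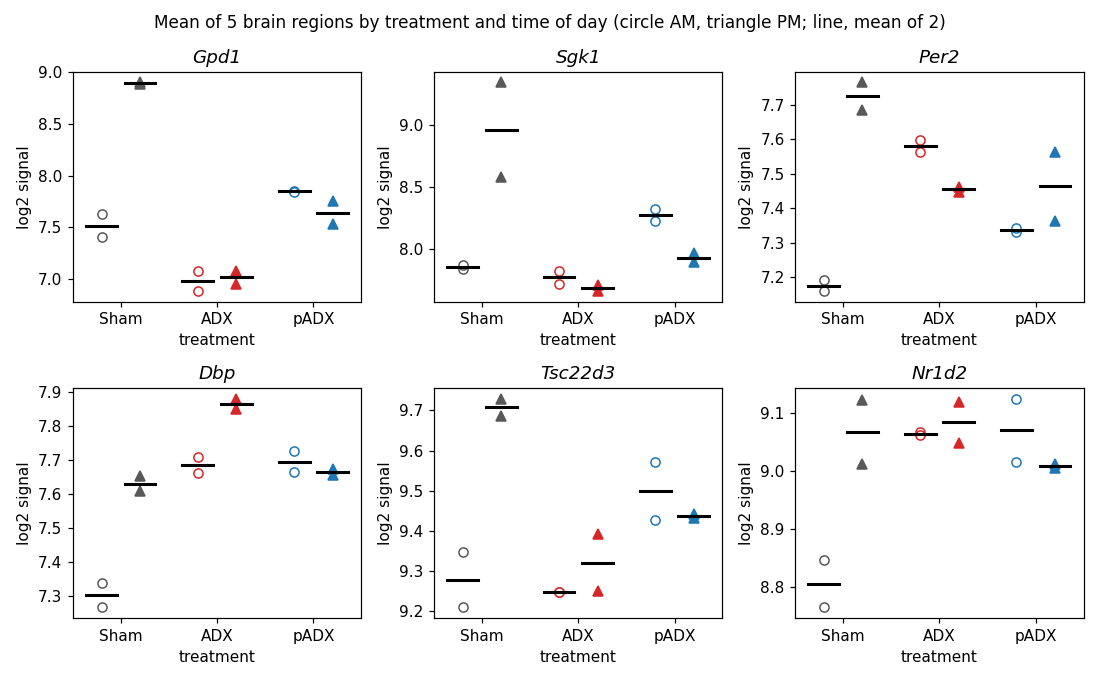
Log2 signal (y axis) of 6 genes by treatment (x axis) and time of day (circles AM, triangles PM), where each point is 1 unit, the mean of 5 brain regions, and each line the mean of 2 units. In Sham the Sgk1 mean was 7.85 at AM and 8.96 at PM.

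For Sham PM vs AM across regions limma called 24 probe sets, 11 up and 13 down, 13 of them with a mean below the 40th percentile. Over 26 alternatives the call of Gpd1 was kept in 23 (adjusted p from 7.66e-22 to 0.0847), that of Mtmr2 in 20 (lost without pADX AM replicate 1 or 2), that of Mmp14 in 19 (lost without pADX AM or PM replicate 1 or 2) and that of Dbp in 8 (0.012 to 0.611). Of the other 6, Slc6a6 kept its call in 13, Adipor2 and Slc16a1 in 10, Rrp8 and Gtf2i in 9 and Cnot10 in 7. Gpd1 lost its call without pADX AM replicate 1 (0.0524), without pADX AM replicate 2 (0.0527) and with the septum, hypothalamus and amygdala alone (0.0847), and Dbp with every unit left out except Sham AM replicate 2 and Sham PM replicate 2. Sgk1 (adjusted p = 0.218), Per2 (0.0551), Tsc22d3 (0.147), Fkbp5 (0.33, 0.476), Per1 (0.354), Nr1d2 (0.226) and Bmal1 (0.225) did not pass over all probe sets.

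Within ADX, Trio fell from AM to PM (-0.55, adjusted p = 0.00792), and Polr1f, a subunit of RNA polymerase I, rose (0.27, adjusted p = 0.0311), among 9 probe sets called. Another well detected probe set of Trio stood at 0.04 (adjusted p = 0.956). Within pADX none of the 3 called was a named gene. From AM to PM, camera called oligodendrocyte markers down in ADX (adjusted p = 0.00663; adjusted p = 0.723 with an estimated correlation). In pADX it called immediate early genes up (0.00465; adjusted p = 0.127 with an estimated correlation), neuropeptide genes up (0.0441; adjusted p = 0.355 with an estimated correlation) and microglia and macrophage markers down (0.0433; adjusted p = 0.7 with an estimated correlation). The PM minus AM change of Trio differed between ADX and Sham (-0.60, SE 0.04, adjusted p = 0.023), and that of Gpd1 between pADX and Sham (-1.58, SE 0.15, adjusted p = 0.0461). The difference for the other Trio probe set was -0.12 (adjusted p = 0.886). In pADX, Gpd1 had a mean of 7.85 at AM and 7.64 at PM, and in ADX 6.98 and 7.02. The same difference for Sgk1 was -1.20 for ADX (adjusted p = 0.48) and -1.45 for pADX (0.459), and for Per2 -0.68 (0.121) and -0.42 (0.456). Adjusted over all probe sets, these were not shown to differ from Sham. Adjusted over the list alone, the change from AM to PM differed between ADX and Sham for 8 clock genes, lower for Dbp, Nr1d2, Per1, Per2 and Rorb and higher for Bmal1, Npas2 and Nr1d1 (camera adjusted p = 0.123), and for Gpd1 (-1.34) of the glucocorticoid-induced genes. Camera called the immediate early list (adjusted p = 0.000634) and the glucocorticoid-induced list (0.0119) lower in ADX by time, with an adjusted p = 0.0701 and an adjusted p = 0.347 with an estimated correlation.

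For pADX by time, adjusted over the list alone, Gpd1, Sgk1, Tsc22d3 and Plekhf1 were lower and, of clock genes, Dbp, Nr1d2 and Per2 lower and Bmal1 higher. Camera called the glucocorticoid-induced list (adjusted p = 2.62e-07) and the clock list (0.0099) lower, each with an adjusted p = 0.106 with an estimated correlation, and oligodendrocyte markers higher (0.00915), with an adjusted p = 0.677 with an estimated correlation. The interactions gave 11 calls for ADX by time of day across regions, 10 below the 40th percentile, and 14 for pADX, 12 below it. The first count was 0 with a variance prior without a trend (2097 at an unadjusted p under 0.05 in the reported limma fit), which ended the call of Trio. It was 64, 108, 149, 93, 108, 100, 95 and 188 without each Sham or ADX unit in turn (Sham AM 1, ADX AM 1, Sham PM 1, ADX PM 1, Sham AM 2, ADX AM 2, Sham PM 2, ADX PM 2). Trio kept its call in 21 of 26 alternatives (adjusted p from 3.49e-07 to 0.229), 12 of them with a unit left out.

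Over the 3 treatments together, 3 genes passed the test for time of day, though 21 of 100 splits of the same samples gave at least 3 calls. Sdf2l1, which helps fold proteins in the endoplasmic reticulum, fell from AM to PM (-0.33, SE 0.03, adjusted p = 0.0269), as did Cyld, a deubiquitinase gene (-0.17, adjusted p = 0.0252), and Rtn4, which codes for the neurite growth inhibitor Nogo (-0.12, adjusted p = 0.00633). Other well detected probe sets stood at 0.00 for Cyld and -0.01 for Rtn4. Dbp (0.16, adjusted p = 0.345), Per2 (0.18, 0.556), Sgk1 (0.23, 0.791), Fkbp5 (0.11, 0.727), Tsc22d3 (0.15, 0.554) and Bmal1 (-0.08, 0.706) did not pass. Passing when adjusted over the list alone, Junb (0.16) and Nr4a1 (0.31) of the immediate early genes, Ddit4 (0.43) and Gadd45g (0.17) of the glucocorticoid-induced genes, Cck (0.23) and Vip (0.23) of the neuropeptide genes and Bhlhe41 (0.06) rose, and Clock (-0.16), Esam (-0.15), Ugt8 (-0.15) and Fgfr1 (-0.14) fell, while the vascular growth factor receptor gene Flt1 (0.39) rose. Camera called immediate early (adjusted p = 0.0069) and glucocorticoid-induced genes (0.0197) up and oligodendrocyte (0.00575) and choroid plexus markers (0.0294) down. With an estimated correlation these had an adjusted p = 0.42 for the first 2 and an adjusted p = 0.897 for the last 2. The count of 3 for PM vs AM across regions became 0 without pADX AM replicate 1 or ADX AM replicate 2, 1 without Sham AM replicate 1, ADX AM replicate 1, ADX PM replicate 1, pADX AM replicate 2, Sham PM replicate 2, ADX PM replicate 2 or pADX PM replicate 2. Sdf2l1 and Cyld kept their calls in 9 of 26 alternatives each and Rtn4 in 14, and Rtn4 lost it without pADX AM replicate 1 or ADX AM replicate 2.

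Split by time of day, Sult1a1 was lower in ADX than in Sham at AM (4.01-fold, adjusted p = 0.0136) and at PM (4.34-fold, adjusted p = 0.00686), and Htra1 at AM (-1.23) and PM (-0.98). At AM Dbp was higher in ADX (0.38, adjusted p = 0.0256), and Prodh (-1.02), Aifm3 (-0.97), the amino acid transporter gene Slc6a20a (-0.74), Mt2A (-0.54), Glul (-0.52), the phosphatase gene Dusp3 (-0.41) and the phosphate transporter gene Slc20a2 (-0.25) were lower. Another well detected probe set stood at -0.28 for Slc6a20a (limma adjusted p = 0.719), -0.21 for Dusp3 (0.755) and -0.13 for Slc20a2 (0.801). Those of Glul stood at -0.48 and -0.57 (0.58 and 0.314). Also higher at AM were Ctc1, which protects telomeres (0.22), and Ppme1 (0.20). At PM Gpd1 was 3.67-fold lower in ADX (-1.87, SE 0.11, adjusted p = 0.00352), Phyhd1 (-0.80), Trio (-0.55) and Rtkn (-0.31) were lower, and the other Trio probe set stood at -0.16 (adjusted p = 0.546). Higher at PM were Fabp7, the fatty acid binding protein of radial glia and astrocytes (0.67), and Slc16a1 (0.34). Sgk1 stood at -0.08 at AM and -1.28 at PM (adjusted p = 0.135). The totals were 30 probe sets at AM, 17 below the 40th percentile, and 19 at PM, 11 below it. Both comparisons set 2 ADX units against 2 Sham units. Neither was fitted under the alternatives or to other splits, so how far these calls hold was not tested.

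Within single regions, the fall of Sult1a1 in ADX passed in the septum (-2.19, SE 0.13, adjusted p = 0.00173), hypothalamus (-2.22, adjusted p = 0.0266), amygdala (-2.18, adjusted p = 0.0222) and dorsal raphe (-2.15, adjusted p = 0.034). Its hippocampal means were 7.60 (SD 0.16, n = 4) in Sham and 5.60 (SD 0.52, n = 4) in ADX (adjusted p = 0.0953 from limma), and its change stood at -1.65 in the frontal cortex (0.0716) and -1.57 in the locus coeruleus (0.0767). The change was not shown to differ between regions (interaction adjusted p = 0.226). Htra1 fell in the septum (-1.22), hypothalamus (-1.11), amygdala (-1.33, adjusted p = 0.00095) and hippocampus (-1.32, adjusted p = 0.0108), and stood at -1.17 in the frontal cortex (0.0588), -0.91 in the dorsal raphe (0.191) and -0.96 in the locus coeruleus (0.0767). Paqr8 fell in the frontal cortex (-0.66, adjusted p = 0.0114), hypothalamus (-0.73, adjusted p = 0.00376) and amygdala (-0.71, adjusted p = 0.0402). Mepe, known as a matrix glycoprotein of bone, fell in the septum (-1.37, adjusted p = 0.0177) and was at 0.00 there with the higher floor. With 1 ADX array at the floor, the -1.37 is a lower bound of its fall. Ctss, a lysosomal protease of microglia, fell in the hypothalamus (-0.49, adjusted p = 0.0215), and Acot13, an acyl-CoA thioesterase, in the frontal cortex (-0.32, adjusted p = 0.0416). The glucocorticoid-induced list had medians of -0.42 in the frontal cortex, -0.22 in the septum and -0.18 in the amygdala, all at the common scale. They were -0.13 in the hypothalamus, -0.17 in the hippocampus, -0.18 in the dorsal raphe and -0.19 in the locus coeruleus. In this order of regions, and adjusted over the list alone, 14, 8, 4, 6, 6, 7 and 10 members fell and 1 rose (Lyve1 in the septum).

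The ADX change of Fkbp5 differed between regions (interaction adjusted p = 0.00133 over 80 arrays, and 0.00884 without the frontal cortex). Its change in ADX was -1.22 in the hippocampus (adjusted p = 0.0603), -1.01 in the frontal cortex (0.137), -0.67 in the amygdala, -0.35 in the locus coeruleus, -0.29 in the septum, -0.25 in the hypothalamus and -0.14 in the dorsal raphe, none of which passed alone over all probe sets. Adjusted over the glucocorticoid-induced list alone, Fkbp5 fell in the frontal cortex, hippocampus and locus coeruleus but not in the other regions. Nr3c2 differed between regions too (interaction adjusted p = 0.0454), with 0.62 in the hippocampus, 0.50 in the amygdala and 0.06 in the frontal cortex; without frontal cortex Sham PM replicate 2 its adjusted p was 0.0805. In the hypothalamus the corticotropin-releasing hormone gene Crh stood at 1.03 (adjusted p = 0.498) and Avp at -0.52 (0.584). Adjusted over the HPA axis list or the neuropeptide list alone, Crh did not pass against Sham but was higher in ADX than in pADX. The serotonin transporter gene Slc6a4 stood at -0.10 (adjusted p = 1) in the dorsal raphe, and Th and Dbh, of noradrenaline synthesis, at 0.95 (0.909) and 0.75 (0.993) in the locus coeruleus. There, scaling state and treatment cannot be told apart, since no ADX array was at the common value.

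**Figure D3:**
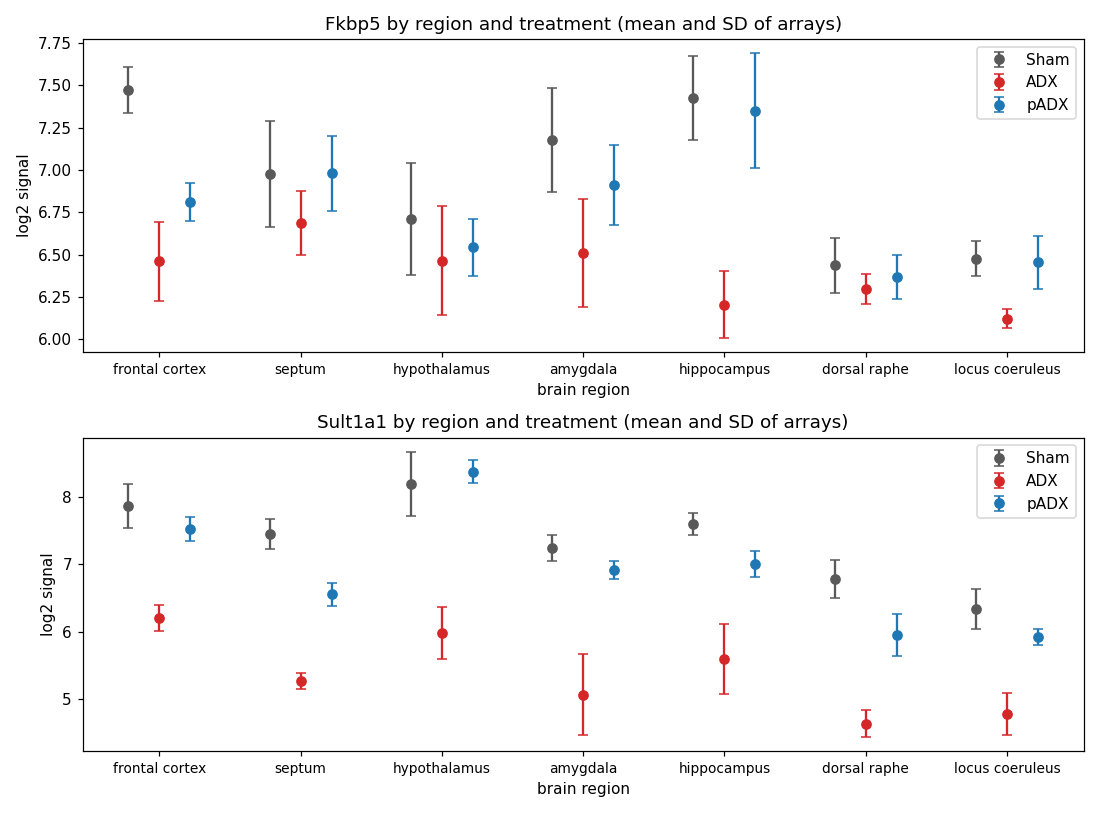
Log2 signal (y axis) of Fkbp5 and Sult1a1 in 7 brain regions (x axis) by treatment, as the mean (point) and SD (bar) of 2 to 4 arrays. Hippocampal Fkbp5 had a mean of 7.42 in Sham and 6.21 in ADX, and dorsal raphe Fkbp5 of 6.44 and 6.30.

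For ADX vs Sham, limma called 5 probe sets in the frontal cortex, 7 in the septum, 5 in the hypothalamus, 4 in the amygdala, 1 in the hippocampus, 2 in the dorsal raphe and 0 in the locus coeruleus (1865 at an unadjusted p under 0.05, lowest adjusted p 0.0767). The frontal cortex count was 770 without Sham PM replicate 1. Single arrays left out moved the septum to between 1 (Sham PM replicate 1) and 27 (ADX PM replicate 2), the hypothalamus to between 1 (Sham PM replicate 1) and 8 (Sham AM replicate 1) and the amygdala to between 1 (pADX AM replicate 1) and 16 (Sham PM replicate 1). For pADX vs Sham the counts were 0 in the frontal cortex (3606 unadjusted), 0 in the septum (1691), 0 in the hypothalamus (1423), 0 in the amygdala (2341), 0 in the locus coeruleus (1291), 6 in the hippocampus and 1 in the dorsal raphe, all 7 below the 40th percentile. The frontal cortex count was 774 without Sham PM replicate 1. For pADX vs Sham in hippocampus the count was 255 without pADX PM replicate 1 and 168 without pADX PM replicate 2. For ADX against pADX, Sult1a1 fell in the septum (-1.29, adjusted p = 0.047) and hypothalamus (-2.39, 0.0205), Htra1 in the amygdala (-1.17, 0.00288) and hippocampus (-1.05, 0.0434). Lower too were Paqr8 in the hypothalamus (-0.57, 0.0205), Mepe in the septum (-1.26, 0.047) and Mrpl43, a mitochondrial ribosomal protein gene, in the hippocampus (-0.61, 0.0496), while Agap3 rose in the locus coeruleus (0.49, 0.0412). The Mepe value is a lower bound of its fall, with 1 ADX array at the floor. For PM vs AM, Atg101, an autophagy gene, rose (0.44, adjusted p = 0.0225) and the kinase gene Tnik fell (-0.55, adjusted p = 0.0355) in the dorsal raphe among 3 calls. Both Sham PM arrays of that region and no other array of it were at the common scale, so scaling and time coincided in its Sham arrays. The hypothalamus had 1, below the 40th percentile, and the frontal cortex, septum, amygdala, hippocampus and locus coeruleus 0 (1717, 2423, 1461, 1942 and 2095 unadjusted).

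The regions differed in their leading transcripts. A fold marked "at least" is set against a next region with some arrays at the floor. The hypothalamus was highest in Pmch, the melanin-concentrating hormone gene (12.19, SD 0.19, n = 12, against 6.85 in the next region, 40.5-fold), and in Oxt (28.2-fold), Avp (13.7-fold), Hdc, which makes histamine (at least 11.7-fold, 1 of 12 at the floor), the orexin gene Hcrt (10.7-fold) and Trh (at least 9.67-fold, 1 of 12). The pituitary hormone subunit gene Cga had a mean of 9.20 there with an SD of 1.74, the widest among the leading genes of the regions. It was at the floor on 1 of 12 arrays there and 6 of 10 in the next region, so no fold is given. The locus coeruleus was highest in Dbh, which makes noradrenaline (8.34, SD 1.11, n = 12, at least 17.7-fold, 7 of 10 at the floor), Irx4 (at least 4.55-fold, 5 of 12), Calca (2.80-fold) and Phox2a (at least 2.51-fold, 7 of 12), while Th stood at 8.74 there and 8.77 in the hypothalamus. The dorsal raphe was highest in Slc6a4 (10.66, SD 0.44, n = 12, against 9.61 in the locus coeruleus, 2.07-fold), the serotonergic factor gene Fev (2.02-fold), Foxa2 (at least 3.94-fold, 4 of 12), Tcf7l2 (at least 3.14-fold, 4 of 10) and Ucn (at least 2.42-fold, 2 of 10).

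The hippocampus was highest in the protease gene Klk8 (at least 5.56-fold, 11 of 12 at the floor), the granule cell gene Prox1 (2.54-fold), Mas1 (2.64-fold), Htr5b (2.96-fold) and Nr3c2 (9.28, SD 0.34, n = 10, against 8.31 in the septum, 1.95-fold). The frontal cortex was highest in Egr1 (10.87, SD 0.22, n = 10, 2.32-fold), the upper layer gene Cux2 (2.41-fold), Tbr1 (1.97-fold), Wnt10a (at least 4.08-fold, 10 of 12) and Cyp11b1 (at least 3.94-fold, 5 of 12). The septum was highest in the adenosine receptor gene Adora2a (at least 4.88-fold, 5 of 12), Zic4 (3.85-fold), Prkcd (3.52-fold), Zic1 (2.39-fold) and Gpr6 (no fold given, 10 of 12 next and 1 of 12 septum arrays at the floor); Adora2a and Gpr6 are on the striatum list and Prkcd on the thalamus list as well. The amygdala led in Rgs18 (at least 2.86-fold, 3 of 10), Ccn2 (2.04-fold) and Myo16 (2.02-fold). Of the fixed markers, those highest in their own region numbered 6 of 8 for the frontal cortex, 2 of 6 for the septum, 10 of 11 for the hypothalamus, 1 of 7 for the amygdala (Etv1, 1.52-fold), 6 of 9 for the hippocampus, 5 of 7 for the dorsal raphe and 5 of 8 for the locus coeruleus. A lead of any size counted. Small ones were Trpc4 in the septum (1.01-fold) and Wfs1 (1.05-fold), Grik4 (1.05-fold) and Fibcd1 (1.11-fold) in the hippocampus. Hoxb2 in the locus coeruleus was at the floor on 9 of 12 arrays there. Among markers not highest in their own region, Pomc was at the floor of 4 on every hypothalamus array. Chat, Dlk1 and Glp1r in the septum and Htr1a in the dorsal raphe were others. The largest leads not given above were Tnnc2, Olr59 and Gypc (frontal cortex), Cdca7 (septum) and Ctxnd1 and Lrrc10b (hippocampus). Cthrc1 and Grifin (dorsal raphe) and Skor1 and Ifi27l2b (locus coeruleus) completed them.

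**Figure D4:**
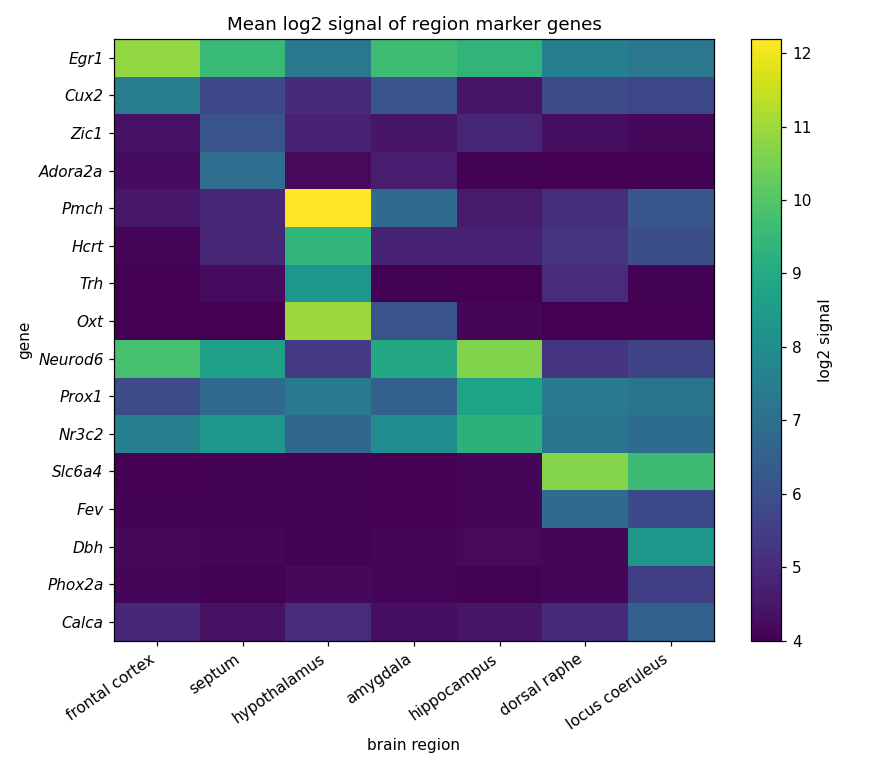
Mean log2 signal (colour) of 16 marker genes (y axis) in 7 brain regions (x axis), each the mean of 10 or 12 arrays. Pmch reached 12.19 in the hypothalamus and Dbh 8.34 in the locus coeruleus.

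Region means differed for 20268 of 31042 probe sets by the moderated F test. Scaling state largely went with region and the 3' to 5' ratio of beta-actin differed between regions. The test held no term for either. Probe sets at least 1 log2 unit above every other region numbered 79 in the frontal cortex, 38 in the septum, 50 in the hypothalamus, 5 in the amygdala, 32 in the hippocampus, 12 in the dorsal raphe and 12 in the locus coeruleus; the amygdala count was 3 without the Sham AM replicate 2 arrays. Treatment changes differed between regions for 956 probe sets in ADX and 482 in pADX, and time of day changes for 97. Without frontal cortex Sham PM replicate 2 these counts were 348, 211 and 337, and without the frontal cortex 112, 18 and 6. Among named genes the clock gene Nr1d2 differed between regions by time of day (interaction adjusted p = 0.00461) and Sult1a1 in pADX (0.0484); without the frontal cortex these were 0.277 and 0.237.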

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

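The tests of explanations, the search for units that stand apart, pADX by time of day and the interactions by region were chosen only after the results were seen. ADX by time of day was set beforehand.

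Some units stood apart within groups of 4, about as many as chance gives. Each group joined the AM and PM units of 1 treatment, so a time of day difference enters its spread. Of 87 such groups over 29 genes, 5 had a unit whose gap to the nearest of the others took up more of the group's range than the critical value of Dixon's test; chance gives about 1 in 20 groups. Snapc2 in pADX AM replicate 2 (7.91, others at least 7.99) had a ratio of 0.860 and Tsc22d3 in ADX PM replicate 1 (9.39, others near 9.25) a ratio of 0.989. Tsc22d3 in pADX AM replicate 2 (9.57, others 9.43 to 9.44) had 0.896, Per2 in pADX PM replicate 2 (7.56, others 7.33 to 7.36) 0.859 and Nr1d2 in pADX AM replicate 1 (9.13, others 9.01 to 9.02) 0.916.

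Other results differed between groups by an interaction test. The change of Trio from AM to PM differed between ADX and Sham by -0.60 log2 units, and that of Gpd1 between pADX and Sham by -1.58. Another well detected probe set of Trio differed by -0.12 (adjusted p = 0.886), so the Trio result rests on 1 probe set. The ADX change of Nr3c2 (adjusted p = 0.0454) and the time of day change of Nr1d2 (0.00461) differed between regions. Without frontal cortex Sham PM replicate 2 these were 0.0805 and 0.000347, and without the frontal cortex 0.15 and 0.277. In data outside the comparisons, unassigned frontal cortex array 1 held more Hbb (12.40) and Alas2 (7.16) than the highest of the 10 grouped frontal cortex arrays (11.84 and 6.76).

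Hbb and Alas2, both transcripts of red cells, were lower in ADX than in Sham, with Hbb at -1.73 (SE 0.27) and Alas2 at -1.62 (SE 0.20). Unequal scaling is argued against by the septum and amygdala, whose arrays shared a scale: as deposited there, Hbb stood at -1.91 (SE 0.31) and Alas2 at -1.68 (SE 0.24), a lower bound of its fall with 4 of 8 ADX arrays at the floor. Less blood of all kinds in the ADX tissue cannot be told apart from fewer transcripts per red cell, because the neutrophil genes S100a8 and S100a9 had a mean change of -0.19 and lay at the floor on 55 and 32 of 60 arrays. Slc4a1, another blood marker, showed no such fall and stood at -0.10 (SE 0.15). Its mean of 4.78 lay below the 40th percentile (4.83), with 12 of 60 arrays at the floor, so it cannot decide the question. A change in the blood itself that comes with ADX stays open and untested.

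Gpd1 and Dbp were higher at PM than at AM in Sham. A single Sham unit as the whole source is argued against, since at least 0.892 of either change was left without any 1 of the 4 Sham units (Gpd1 1.26 to 1.49, Dbp 0.29 to 0.36). Unequal scaling as the whole source is argued against by the septum and amygdala, whose arrays shared a scale. As deposited there, Gpd1 stood at 1.14 (SE 0.15) and Dbp at 0.19 (SE 0.08), each more than 2 SE above 0, against 1.38 and 0.33 over 5 regions. The margin for Dbp was small. A daily rhythm in the Sham tissue may account for the change, a hypothesis that rests on 2 units per time.

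The ADX change of Fkbp5 differed between regions (adjusted p = 0.00133). Unequal scaling as the sole source is argued against only among the frontal cortex, septum and amygdala, all at the common scale. Their as-deposited changes ran over 0.743 log2 units (SE 0.21), from -1.01 in the frontal cortex to -0.27 in the septum. The SE does not allow for picking the extremes. The check leaves out the hippocampus, which had the largest fall and whose ADX arrays had trimmed means from 34.1 to 171. The frontal cortex Sham array least correlated with its region is argued against as the sole source, since without it the adjusted p was 0.00406. A different dependence of the regions on adrenal hormones may account for it and was not tested.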

How the results depend on the processing

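Values as deposited, the septum, hypothalamus and amygdala alone, and the interactions without a frontal cortex array or without the frontal cortex were chosen after seeing the data. Every alternative set beforehand was run. Over all alternatives, counts stayed within 1.5 times the reported one in 376 cases and moved further in 312. Values of named genes kept direction and side of the threshold in 2376 cases, lost the call in 634, gained one in 55 and reversed in 39. For lists, 388 were kept, 52 lost and 2 reversed. The fall of Sult1a1, Htra1, Phyhd1 and Paqr8 in ADX vs Sham across regions and the camera call of glucocorticoid-induced genes were kept throughout. Over the 26 alternatives the ADX change of Sult1a1 ranged from -2.30 to -1.17, of Htra1 from -1.38 to -1.04, of Alas2 from -1.91 to -0.37 and of Igfbp5 from 0.39 to 0.77. Array signal over background limits transcripts near the floor, where 27.5% of values lay. Where a count or a direction moved, the cause was not tested unless the alternative's construction shows it.

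With a floor 4 times higher, which holds dim probe sets at 1 value, ADX vs Sham called 8 across regions, 2 in the amygdala, 1 in the dorsal raphe, 1 in the frontal cortex and 3 in the hippocampus. ADX vs pADX called 8, pADX vs Sham 0 across regions, 1 in the hippocampus and 1 in the septum, ADX by time of day 6 and PM vs AM in the hypothalamus 0. Probe sets highest in a region then numbered 46 in the frontal cortex, 13 in the septum, 22 in the hypothalamus, 1 in the amygdala, 16 in the hippocampus, 3 in the dorsal raphe and 5 in the locus coeruleus. With the filter on dim probe sets, so that fewer were tested, ADX vs Sham called 111 (24 up, 87 down, 29 shared with the reported 41). By region it called 14 in the amygdala, 20 in the dorsal raphe, 12 in the frontal cortex, 42 in the hippocampus, 27 in the hypothalamus, 29 in the locus coeruleus and 83 in the septum. ADX vs pADX called 69 (10 shared), ADX by time of day 4, pADX vs Sham 1 across regions and 0 in the dorsal raphe and hippocampus, and PM vs AM in the dorsal raphe 0. Highest in a region were 17 in the septum, 27 in the hypothalamus, 3 in the amygdala, 6 in the dorsal raphe and 6 in the locus coeruleus. With a lead of 2 log2 units, a stricter criterion, they were 2 in the frontal cortex, 5 in the septum, 13 in the hypothalamus, 0 in the amygdala, 2 in the hippocampus, 0 in the dorsal raphe and 2 in the locus coeruleus.

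With median scaling ADX vs Sham called 41 across regions (12 up, 29 down, 33 shared), 14 in the frontal cortex and 27 in the septum, pADX vs Sham 1 in the hypothalamus, PM vs AM 0 in the dorsal raphe, 0 in the hypothalamus and 1 in the septum, and 119 were highest in the frontal cortex. As deposited, which keeps the unequal scales, ADX vs Sham called 13715 across regions (44 up, 13671 down, 38 shared; median of all probe sets -0.21), 7729 in the dorsal raphe, 0 in the hippocampus, 244 in the hypothalamus, 4515 in the locus coeruleus and 29 in the septum. ADX vs pADX called 3581 (17 up, 3564 down; median -0.12). For pADX vs Sham the counts were 0 across regions (median -0.07), 9 in the dorsal raphe, 1 in the frontal cortex, 0 in the hippocampus, 4 in the hypothalamus and 1 in the septum. For PM vs AM they were 0 across regions, in the dorsal raphe and in the hypothalamus. Highest in a region were 131 in the frontal cortex, 71 in the septum, 32 in the hypothalamus, 20 in the amygdala, 6 in the hippocampus and 6 in the dorsal raphe. As deposited, these genes reversed in ADX vs Sham across regions: Snapc2 to -0.064, Bhlhe41 to -0.16, Ccnyl1 to -0.16, Nr3c1 to -0.17, Nr3c2 to -0.036, Per2 to -0.22 and Nr1d2 to -0.15. In pADX vs Sham, Nr3c1 reversed to -0.016, Nr3c2 to -0.047 and Nr1d2 to -0.018. In ADX vs pADX, Bhlhe41 reversed to -0.020, Ccnyl1 to -0.033, Nr3c1 to -0.16, Dbp to -0.076, Per2 to -0.049 and Nr1d2 to -0.13. The medians reversed to -0.085 for oligodendrocyte markers and to -0.022 for microglia and macrophage markers.

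With 6 means of treatment by time, ADX vs Sham called 22 in the amygdala, 41 in the dorsal raphe, 499 in the frontal cortex, 31 in the hippocampus, 32 in the hypothalamus, 8 in the locus coeruleus and 45 in the septum. PM vs AM called 14 across regions, 27 in the amygdala, 49 in the dorsal raphe, 446 in the frontal cortex, 13 in the hippocampus, 17 in the hypothalamus, 16 in the locus coeruleus and 19 in the septum. pADX vs Sham called 9 across regions, 39 in the amygdala, 22 in the dorsal raphe, 351 in the frontal cortex, 19 in the hypothalamus, 11 in the locus coeruleus and 12 in the septum. With 1 model over all 80 arrays, which shares the spread over regions, ADX vs Sham called 57 in the amygdala, 120 in the dorsal raphe, 1879 in the frontal cortex, 370 in the hippocampus, 72 in the hypothalamus, 60 in the locus coeruleus and 233 in the septum. PM vs AM called 14, 762, 253, 65, 9, 7 and 39 in the same order of regions. pADX vs Sham called 48, 71, 1583, 106, 12, 12 and 28. With all 80 arrays and duplicateCorrelation (consensus correlation 0.00742 for the additive fit), ADX vs Sham called 611 (244 up, 367 down, 32 shared), ADX vs pADX 357, PM vs AM 347, pADX vs Sham 55 and ADX by time of day 83, and Nr3c2 in ADX by time of day reversed to 0.034.

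Without a trend in the variance prior ADX by time of day called 0 (limma) and ADX vs Sham in the hippocampus 8, and without the 2 pADX arrays of the hippocampus the latter called 3. With the septum, hypothalamus and amygdala alone, fewer regions, ADX vs Sham called 17 (0 up, 17 down, 11 shared). Nr3c1 in ADX vs pADX then reversed to -0.016. Without the amygdala ADX vs pADX called 7, PM vs AM 0 and pADX vs Sham 0, and Nr3c1 in ADX vs pADX reversed to -0.0099. Without the dorsal raphe ADX by time of day called 7, ADX vs pADX 9 and PM vs AM 0. Without the hypothalamus ADX vs Sham called 17 and Per1 in PM vs AM reversed to -0.029. Without the locus coeruleus ADX vs Sham called 10 and Nr3c1 in ADX vs pADX reversed to -0.031. Without the septum PM vs AM called 5 and pADX vs Sham 1, Nr3c1 in ADX vs pADX reversed to -0.00406 and Tsc22d3 in pADX vs Sham to 0.017. The interactions by region without frontal cortex Sham PM replicate 2 called 348 for ADX, 211 for pADX and 337 for time of day, and without the frontal cortex 112, 18 and 6.

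With a replicate block ADX vs Sham called 21 across regions (6 up, 15 down, 19 shared), 1 in the amygdala, 2 in the frontal cortex, 1 in the hypothalamus and 2 in the septum. ADX by time of day called 5, ADX vs pADX 10 (9 shared), and PM vs AM 6 across regions, 2 in the amygdala and 0 in the hypothalamus. The labels do not say whether a replicate number pairs samples. Differences between replicates of 2 groups in 1 region correlated with a median between -0.04 and 0.01 per region, those of 2 regions of the same treatment and time with a median of 0.0802 over 108 pairs, and those of other treatments or times with -0.00335 over 542.

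With each unit or array left out in turn, where a lone sample left in a group is assumed to vary like the other groups, the counts across regions ran from 8 to 43 for ADX vs Sham, 1 to 8 for pADX vs Sham, 4 to 28 for ADX vs pADX, 0 to 2 for PM vs AM and 9 to 188 for ADX by time of day. For ADX vs Sham in single regions they ran from 3 to 770 in the frontal cortex, 1 to 27 in the septum, 1 to 8 in the hypothalamus, 1 to 16 in the amygdala, 0 to 3 in the hippocampus, 1 to 7 in the dorsal raphe and 0 to 3 in the locus coeruleus. By array left out, in the order Sham, ADX and pADX AM replicate 1, Sham, ADX and pADX PM replicate 1 and then replicate 2 likewise, the septum gave 2, 11, 4, 1, 23, 3, 2, 10, 5, 7, 27 and 8. The hypothalamus gave 8, 7, 4, 1, 4, 6, 1, 4, 1, 1, 6 and 7, the amygdala 6, 3, 1, 16, 1, 6, 1, 3, 2, 1, 1 and 1, the dorsal raphe 2, 1, 2, 7, 1, 2, 2, 4, 2, 1, 1 and 6 and the locus coeruleus 0, 1, 1, 0, 3, 0, 0, 0, 0, 1, 2 and 1. The frontal cortex gave 3, 770, 11, 3, 12, 20, 5, 25, 13 and 6 in the same order from pADX AM replicate 1 on. The hippocampus gave 0 without Sham AM replicate 1 or 2, Sham PM replicate 1, ADX AM replicate 2 or ADX PM replicate 2, 2 without ADX AM replicate 1 and 3 without ADX PM replicate 1 or either pADX array. In the order of regions given first, pADX vs Sham ran from 0 to 774, 0 to 6, 0 to 2, 0 to 7, 4 to 255, 1 to 5 and 0 to 5. PM vs AM ran from 0 to 3, 0 to 2, 0 to 1, 0 to 1, 0 to 2, 0 to 2 and 0 to 1. Differences among regions ran from 19691 to 20094. Probe sets highest in a region ran from 73 to 87 in the frontal cortex, 31 to 39 in the septum, 48 to 63 in the hypothalamus, 3 to 5 in the amygdala, 25 to 36 in the hippocampus, 10 to 14 in the dorsal raphe and 10 to 13 in the locus coeruleus. Directions turned over these ranges: Per2 in ADX vs Sham -0.0073 to 0.15, Sgk1 in pADX vs Sham -0.48 to 0.00258, Tsc22d3 in pADX vs Sham -0.10 to 0.036 and Per2 in pADX vs Sham -0.13 to 0.033. The others were Nr3c1 in ADX vs pADX -0.015 to 0.065, Per1 in PM vs AM -0.0084 to 0.17, Nr3c2 in ADX by time of day -0.16 to 0.055 and Nr3c2 in Sham PM vs AM -0.20 to 0.014.

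Named genes of single regions also lost calls when 1 array was left out. Sult1a1 in the septum, Htra1 in the amygdala and Paqr8 in the hypothalamus kept theirs without any 1 array. Mepe in the septum lost it without Sham AM replicate 1, Sham PM replicate 1 or Sham AM replicate 2. Htra1 in the hippocampus lost it without any 1 Sham array except Sham PM replicate 2 or without ADX AM or PM replicate 2. Acot13 in the frontal cortex lost it without every pADX array and without ADX PM replicate 1, ADX AM replicate 2 or ADX PM replicate 2. Ctss in the hypothalamus lost it without every Sham array, ADX AM or PM replicate 2 or pADX AM replicate 2. Of 12 arrays left out, the call ended without 8 for Htra1 in the septum and Sult1a1 in the hypothalamus, 9 for Htra1 in the hypothalamus and Sult1a1 in the amygdala and the dorsal raphe, 10 for Paqr8 in the amygdala and Atg101 in the dorsal raphe, and 11 for Tnik in the dorsal raphe.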

Other observations

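Transcripts of tissue next to a region differed in amount between the regions. Ttr, the transthyretin gene made in the choroid plexus, had a mean log2 signal of 12.34 (SD 0.67, n = 10) in the hippocampus and 11.75 (SD 1.55, n = 12) in the amygdala. It stood at 7.26 (SD 1.94, n = 12) in the locus coeruleus, 7.24 (SD 2.50, n = 12) in the septum and 5.07 in the dorsal raphe. Sostdc1, on the same marker list, stood at 7.98 (SD 1.29) in the hippocampus and 7.23 (SD 1.44) in the amygdala and at or below 5.50 in the other regions. In the hypothalamus the thyrotropin subunit gene Tshb stood at 5.21 (SD 1.37) beside Cga, while the pituitary hormone gene Prl was at the floor of 4. The ADX change of Ttr across regions was 0.14 (SE 0.56), with an adjusted p of 1.

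The glutamate transporters of neurons divided the regions. Slc17a7 had a mean of 9.84 (SD 0.22) in the frontal cortex, 9.77 (SD 0.38) in the amygdala and 9.67 (SD 0.28) in the hippocampus, and of 4.05 in the hypothalamus, 4.41 in the dorsal raphe and 4.95 in the locus coeruleus. Slc17a6 ran the other way, with 10.69 (SD 0.09) in the hypothalamus, 10.59 (SD 0.24) in the dorsal raphe and 10.40 (SD 0.08) in the locus coeruleus, against 6.39 (SD 0.35) in the frontal cortex. The dopamine receptor gene Drd1 was highest in the septum (8.69, SD 0.50) and next in the amygdala (7.19, SD 0.16), and the neuropeptide gene Cck in the frontal cortex (11.77, SD 0.12).

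The 2 frontal cortex arrays without a treatment label differed from each other. In the order of the series they stand where the other regions have Sham AM and ADX AM replicate 1. No treatment was assigned to them on that ground. Array 1 had Sult1a1 at 6.86, Htra1 at 8.94 and Fkbp5 at 6.80, and array 2 at 6.07, 7.61 and 5.92, where the 10 grouped frontal cortex arrays ran from 6.06 to 8.22, 7.82 to 9.24 and 6.21 to 7.61. Hbb was at 12.40 and 9.40 (grouped 9.53 to 11.84), Alas2 at 7.16 and 4.44 (4.01 to 6.76), Per1 at 5.47 and 4 (4.54 to 7.13) and Dbp at 7.37 and 7.59 (7.42 to 8.39).

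Beyond ADX vs Sham, the median, mean and camera direction of a list differed in sign, all without a call. In pADX vs Sham this held for the clock, endothelial, neuron, choroid plexus, meninges, pituitary and thalamus lists, in ADX vs pADX for the meninges list besides ependyma, and in PM vs AM for the HPA axis, astrocyte, microglia and endothelial lists. In ADX by time of day it held for the receptor, trophic factor, endothelial, choroid plexus, blood and cerebellum lists, in pADX by time of day for the striatum list, in ADX PM vs AM for the endothelial list and in pADX PM vs AM for the monoamine, trophic factor, ependyma, cerebellum and striatum lists.

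Other splits of the same samples were fitted in the same way, a test chosen after the results were seen. Across regions, 1 of 35 splits for ADX vs Sham, the real one, gave 41 and the highest other 7. This share is under 0.05 and the smallest these splits can give. It argues against chance but cannot exclude it. For ADX vs pADX 1 of 35 gave 15, a share under 0.05 and the smallest these splits can give. The highest other gave 14, and the real count was 4 without ADX AM or pADX AM replicate 2. The evidence against chance is therefore marginal. Chance cannot be excluded for pADX vs Sham, where 2 of 35 gave at least 2 (highest other 5), or PM vs AM, where 21 of 100 gave at least 3 (highest other 19). For ADX vs Sham in the septum 1 of 35 gave 7 (highest other 3), again the smallest share possible. This argues against chance for that region taken alone, not over the regions tested, and the count ran from 1 to 27 with single arrays left out. Chance cannot be excluded in the hypothalamus (3 of 35 gave at least 5, highest other 7), amygdala (2 of 35 gave at least 4, highest other 34), hippocampus (5 of 35 gave at least 1, highest other 4) or dorsal raphe (3 of 35 gave at least 2, highest other 12). In the locus coeruleus the real count was 0, so that 35 of 35 splits were as large by construction and nothing was tested (highest other 13). The frontal cortex had 10 splits, too few for a share under 0.05, with 5 for the real one and 4 for the highest other.

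Nothing was tested either where pADX vs Sham had a real count of 0, in the frontal cortex (highest other 150), septum (23), hypothalamus (17), amygdala (21) and locus coeruleus (6). In the dorsal raphe 12 of 35 splits were as large (real 1, highest other 36), so chance cannot be excluded. For PM vs AM the real count was 0, and nothing was tested, in the frontal cortex (highest other 473), septum (31), amygdala (18), hippocampus (26) and locus coeruleus (26), where 100 of 100 splits are as large by construction. Chance cannot be excluded where 25 of 100 splits were as large in the hypothalamus (real 1, highest other 32) and 9 of 100 in the dorsal raphe (real 3, highest other 34). Splits that called several times the real count may point to a structure of the samples other than the groups. Unstable estimates of spread in small groups were not told apart from it. For differences among regions the splits argue against chance, with 1 of 100 as large (real 20268, highest other 1). For the 79, 38, 50, 5, 32, 12 and 12 probe sets highest in each region the highest other was 0. These splits shuffled all region labels within a unit at once, which brings the region means together and leaves little room for a lead. They therefore bear on whether regions differ at all and do not test the count of any 1 region. Scaling state largely went with region, so these splits cannot tell the share of region from that of scaling. The comparisons within a treatment or within a time of day, the time of day interactions and pADX in the hippocampus, with groups of 2, were not tested by splits.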
